A study of Mus musculus with 4 samples.

How the data were processed

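Total RNA of mouse spermatogonial stem cells was sequenced by the submitters on an Illumina HiSeq, per the series' design text, in 2 libraries after retinoic acid and 2 after vehicle. Groups and replicate numbers were taken from the sample titles. Each deposited file lists features for 1 library with an identifier, a number of unique reads, a length, the percent of the length covered and an RPKM. The counts are raw whole numbers of uniquely placed reads per feature, per the file headers. In each file they summed to the total in its header and the lowest was 1, so a feature missing from a file was given a count of 0. The RPKM values were made by the authors from those counts, the length and the header total; recomputing them gave relative differences of at most 2.2e-08. The RPKM were not tested. Coverage is printed with a percent sign per the file headers, and 1 value in each retinoic acid file passed 100% (at most 100.25%). The aligner, the annotation, the genome build, the assembly behind the features and any filter are not given in the sources used here.

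The identifiers come without gene names. None was found among the identifiers of the RefSeq table (GRCm38.p6) or of GENCODE release M21, so no gene was named, no coordinate is given, and features could not be classed as coding or non-coding. For that reason the planned count of non-coding features, the named genes and the tests of 26 gene lists (618 genes, 0 of which appear as identifiers) could not be made. Because features have no gene names, 2 identifiers per direction are named. They are the first in the ranking set before the data were examined, by fitted log2 fold change among called features whose libraries did not overlap between groups; that rule had provided for 8 per direction. The comparison, its test, the gene lists and most alternatives were set before the data were examined.

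Counts were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr (32160 features kept, with 98.4% of all reads), TMM factors (0.956 to 1.07), glmQLFit and glmQLFTest with the group as the only term, two-sided, and Benjamini-Hochberg adjustment over all features tested. A feature was called at an adjusted p under 0.05. Standard deviations of shares are of the percents of each library's total count, and those of normalised counts are of counts divided by effective library size and rescaled to its mean. Folds against a group with 0 reads were computed on group sums per total reads, with 3 counts over the group as the floor. The common biological coefficient of variation was 0.261. Shares of counts have 95% Wilson intervals.

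The test was checked on simulated counts for the same comparison, with the real means, library sizes and trended dispersion and 200 changed features among 29526 tested. It recovered 37 of 100 features changed 4-fold and 2 of 100 changed 2-fold, all in the right direction, with 0 false calls. At this size the test thus missed most of the simulated 4-fold changes and nearly all of the 2-fold ones. The changed features were drawn over the whole range of abundance. Simulated features did not scatter around the dispersion trend, and no TMM factors were simulated. The 0 false calls therefore need not hold for the real libraries. The shares recovered also depend on the number of features changed.

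Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), upper-quartile factors, no filter, at least 50 counts in at least 2 libraries, a fold threshold of 2, the replicate number as a block, and leaving out each library. Chosen after seeing the data were library totals alone, counts halved and rounded up, coverage of at least 50% in at least 2 libraries, leaving out the 10 most abundant features, thinning each library to 7918431 reads, and counting runs of consecutive identifiers once.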

Results

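RNA was profiled in mouse spermatogonial stem cells, the germline stem cells of the testis, after 24 hr with all-trans retinoic acid or with ethanol vehicle. Retinoic acid is the vitamin A metabolite that drives spermatogonia towards differentiation and meiosis, and the series asked how long non-coding RNA responds to it. The labels give the retinoic acid dose as 0.3 mM in 0.1% ethanol; no other source was at hand to check that unit, and a slip for µM cannot be excluded. The cells came from C57BL/6 pups aged 6 to 8 days, were enriched for the surface protein Thy1, and were grown on STO fibroblast feeders with GDNF, the growth factor that sustains stem cell renewal. There were 2 libraries per group. Nothing in the labels says whether these came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The vehicle libraries held 8156257 and 8131291 unique reads and the retinoic acid libraries 7918431 and 7923399.

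The files listed 70677 features in all, of which 46902 (66.4%) had reads in every library. A feature is an entry with its own identifier and length, and the identifiers fell into a series that starts with n (27278 features) and a series that starts with TCONS_ (43399 features). The files do not pair the identifiers with gene names, and 0 of the 70677 matched the RefSeq or GENCODE tables used here, so no feature is placed in the genome or assigned to a gene. Reads were concentrated in a few features. The most abundant one, of 1612 bases, took 7.91% ± 0.91 of the counts in vehicle and 8.11% ± 0.52 in retinoic acid (SD, n = 2). The 6 most abundant, all of the n series, together took 26.2% ± 2.1 and 26.0% ± 0.25. The TCONS_ series took 30.2% ± 0.65 of the counts in vehicle and 30.0% ± 0.051 in retinoic acid. For vehicle replicate 1 the share of the most abundant feature was 8.55%, with a 95% Wilson interval of 8.53% to 8.57%, which covers counting error only. A count of 0 in that library allowed up to 3 counts, or 3.68e-05% of its total.

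Even read counts outnumbered odd ones among scarce features in every library. Among features with 1 to 10 reads, between 62.1% and 63.3% held an even number, and among those with 11 to 20 reads between 50.5% and 51.9% did.

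**Figure D1:**
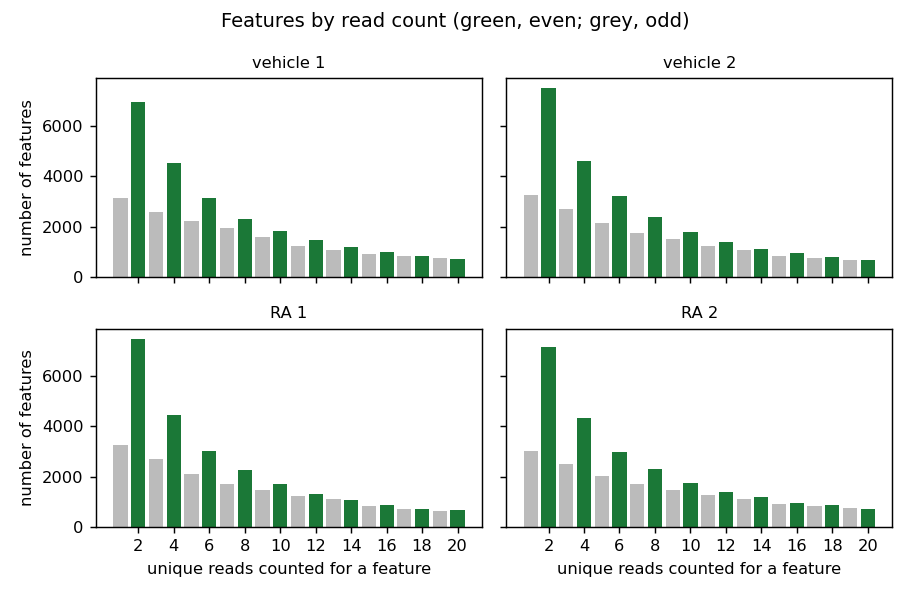
Number of features (vertical axis) holding each number of unique reads from 1 to 20 (horizontal axis), 1 panel per library, with even counts in green and odd counts in grey. In each of the 4 libraries features with 2 reads outnumbered those with 1 or 3 reads.

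Libraries of a group resembled each other more than libraries of different groups. Across the 30484 features with a mean count of at least 10, Pearson's r of the log2 CPM (counts scaled to library size) was 0.931 between the vehicle libraries and 0.935 between the retinoic acid libraries, against 0.905 to 0.916 for the 4 pairs across groups. These are correlations across features, which are not independent replicates. The first principal component held 43.5% of the variance and placed both vehicle libraries (-41.2 and -75.1) apart from both retinoic acid libraries (69.0 and 47.3). The second held 28.3%. It placed the replicate 1 libraries (54.7 for vehicle and 39.2 for retinoic acid) apart from the replicate 2 libraries (-32.6 and -61.3). With 4 libraries few directions remain after the first component. This placing therefore does not by itself show an effect of the replicate number. The libraries of a group were not copies of 1 another. The chi-square of their counts was 7.27 per degree of freedom for the vehicle pair and 7.06 for the retinoic acid pair. Its reference is the counting error of independent reads alone, so it does not show whether the libraries came from separate cultures. A different grouping appeared in library breadth. Vehicle replicate 1 and retinoic acid replicate 2 held 32545 and 32591 features with at least 10 reads, while vehicle replicate 2 and retinoic acid replicate 1 held 29875 and 29295. The median share of a feature's length that was covered, among features with 20 to 40 reads, was 66.2% and 66.0% in the first 2 of these libraries and 63.5% and 62.2% in the others.

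Between retinoic acid and vehicle, 588 of the 32160 features tested (1.83%) differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these, 204 rose and 384 fell, so 65.3% of the changes were decreases. The features that rose did so by a median log2 fold change of 1.99 (quartiles 1.45 and 3.23), and those that fell did so by a median of -1.58 (quartiles -2.22 and -1.27). The change was at least 4-fold for 99 of the features that rose and 118 of those that fell, with features absent from a whole group set at the bound that 3 counts in that group give. The median change over all features tested was 0.0033 on the log2 scale. In 586 of the 588 both retinoic acid libraries lay on the same side of both vehicle libraries, as did 38.9% of all features tested; chance alone gives 33.3% for 2 libraries against 2. At an unadjusted p under 0.05, 3325 features differed, where 1608 would by chance. DESeq2 called 297 features, 288 of them among the 588, and edgeR with library totals in place of TMM factors called 158. The count fell to 350 without vehicle replicate 2, to 289 without retinoic acid replicate 1 and to 372 without retinoic acid replicate 2, and 129 of the 588 were called in each of the 4 fits that left out a library.

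**Figure D2:**
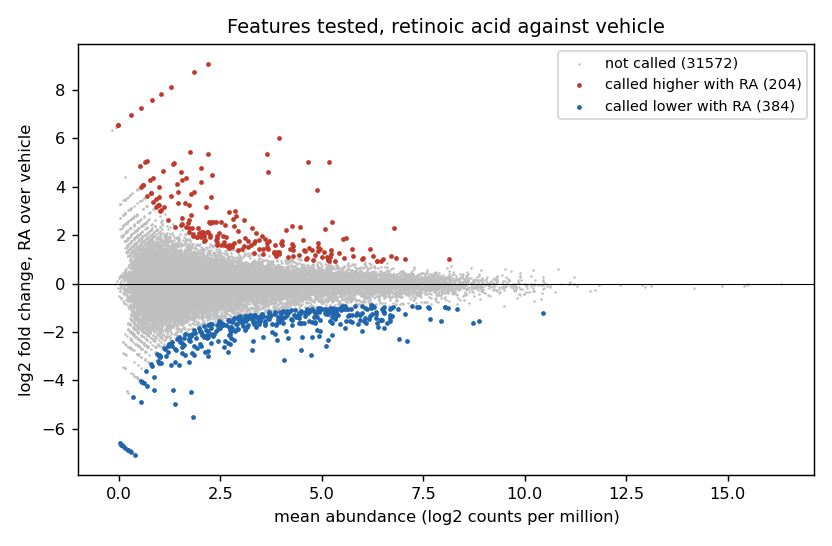
Log2 fold change of retinoic acid over vehicle (vertical axis) against mean abundance in log2 CPM (horizontal axis) for the 32160 features tested, 1 point each. The 204 features called higher are red, the 384 called lower blue and the rest grey; diagonal rows at the left are features with no reads in 1 group.

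The features that fell carried more of the RNA than those that rose. The 384 that fell held 1.87% ± 0.048 of all counts in vehicle and 0.769% ± 0.069 in retinoic acid (SD, n = 2). The 204 that rose held 0.181% ± 0.015 in vehicle and 0.515% ± 0.022 in retinoic acid. Both sets were chosen on these libraries, so the shares are not independent evidence of the direction of the change. They also tend to overstate its size, as do the median fold changes of the called features given above. An exact permutation test of 2 libraries against 2 cannot go below a two-sided p of 0.333, so no such test was run on shares or totals.

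Most changes were found among abundant features, and decreases were most frequent there. When the tested features were ranked by abundance into 3 equal parts, 72 features changed in total in the least abundant part (31 rose, 41 fell), 73 rose and 92 fell in the middle part, and 100 rose and 251 fell in the most abundant part, where 3.27% of features changed. Features that fell had a median abundance of 3.66 log2 CPM and those that rose 2.75. Longer features also changed more often, with 1.14% called among the shortest part (up to 1198 bases), 1.70% in the middle and 2.65% among the longest (from 2111 bases). Decreases made up 59.8%, 65.9% and 67.3% of the calls in these 3 parts. These gradients are counts of calls, and the power to call a feature also grows with its reads. Of the 100 most abundant features 0 rose and 1 fell, with log2 fold changes from -1.21 to 0.59; whether this share lies below that of other features was not tested. The 6 most abundant had log2 fold changes between -0.16 and 0.0014, with a lowest edgeR adjusted p of 0.956.

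**Figure D3:**
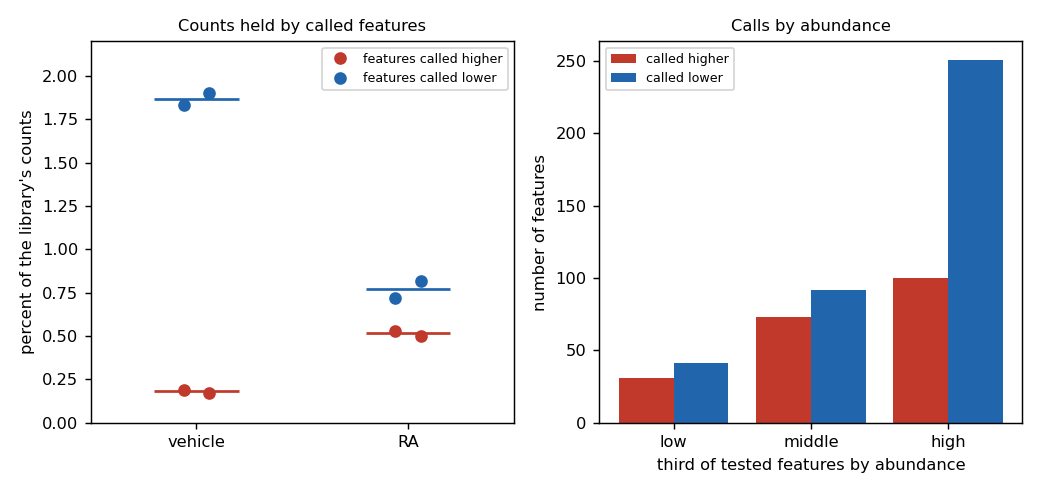
Left, percent of each library's counts (vertical axis) held by the features called higher (red) and lower (blue) in the vehicle and retinoic acid groups; points are libraries and lines are means of 2. Right, number of features called higher and lower (vertical axis) in 3 equal parts of the tested features by abundance; 251 of the 384 features that fell lie in the most abundant part.

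Both identifier series held called features. In the n series 96 features rose and 182 fell of 13658 tested (2.04% called), and in the TCONS_ series 108 rose and 202 fell of 18502 (1.68%). The share called was higher in the n series over all features, with an odds ratio of 1.22 (95% interval 1.03 to 1.44, two-sided Fisher's exact test, p = 0.0183, adjusted p = 0.0459 over 5 tests). The most abundant part, where calls were most frequent, held 6778 of the n features and 3942 of the TCONS_ features tested. That ratio therefore does not show a difference between the series at equal abundance. The order turned in the most abundant part, where 2.80% of n features and 4.08% of TCONS_ features were called (odds ratio 0.677, interval 0.544 to 0.844; Fisher's exact test, p = 0.000384, adjusted p = 0.0019). In the least abundant and the middle part the odds ratios were 1.03 and 1.20, with adjusted p = 1 and 0.426 by the same exact test. The split between decreases and increases did not differ detectably between the series (odds ratio 1.01, interval 0.711 to 1.45; Fisher's exact test, adjusted p = 1). These tests treat features as independent, which features of 1 locus are not. The most abundant part spanned 2.80 to 16.3 log2 CPM, and neither abundance within it nor length was matched between the series. Its odds ratio therefore does not show a difference at equal abundance either.

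Some called features were read in 1 group only, namely 9 of the 204 that rose, with 0 reads in vehicle, and 10 of the 384 that fell, with 0 reads in retinoic acid. There were 4 features with at least 20 reads in each retinoic acid library and 0 in both vehicle libraries, all of them called higher, and 0 features with the reverse pattern. With 3 counts over the vehicle group as the floor, the bounds on their increase ran from 19.2-fold to 47.6-fold with both retinoic acid libraries, from 14.4-fold to 70.6-fold without retinoic acid replicate 1 and from 15.1-fold to 28.1-fold without retinoic acid replicate 2. This floor and every other lower bound given here treat reads as independent; where both reads of a pair were counted, which the even counts leave open, the bounds would be lower. By the same criterion the other pairings of the 4 libraries gave 0 and 1 features.

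By fitted log2 fold change, which ranks features with 0 reads in a group first and depends on the prior count, the top increase was that of TCONS_00166598, a feature of 1558 bases with 36 and 103 reads in the retinoic acid libraries and 0 in both vehicle libraries. Its normalised count was 67.8 ± 42.1 with retinoic acid (SD, n = 2). By summed reads per total reads it lay 47.6-fold above the floor of 3 counts over the vehicle group (edgeR adjusted p = 1.32e-07). It lay 24.7-fold above that floor when retinoic acid replicate 2 was left out. TCONS_00166450, of 1548 bases, had 41 and 66 reads with retinoic acid and 0 in both vehicle libraries. Its normalised count was 52.9 ± 13.6 with retinoic acid. By summed reads per total reads it lay 36.7-fold above the same floor (edgeR adjusted p = 6.16e-07), or 28.1-fold without retinoic acid replicate 2. Reads covered 79.1% and 97.4% of the length of the former and 88.0% and 96.4% of the latter. The top decreases in the same ranking had fewer reads, and other decreases may exceed their bounds. TCONS_00016556, of 665 bases, had 23 and 11 reads in vehicle and 0 in both retinoic acid libraries, a bound of 11-fold lower (edgeR adjusted p = 0.0111), and TCONS_00038909, of 1951 bases, had 20 and 11 reads against 0, a bound of 10.1-fold lower (edgeR adjusted p = 0.0164); without vehicle replicate 1 both bounds were 7.14-fold. Exact binomial 95% intervals on the summed reads also count the error of the higher group. They reached down to 38.2-fold, 29.3-fold, 8.49-fold and 7.70-fold for the 4 features in the order named. These intervals cover counting error only and leave out the spread between libraries of a group. Each limit lies above the lowest bound given here with 1 library left out. In vehicle the normalised count was 16.9 ± 7.8 for TCONS_00016556 and 15.4 ± 5.7 for TCONS_00038909 (SD, n = 2). Reads in the vehicle libraries covered 91.3% and 65.4% of the length of the former and 52.4% and 23.4% of the latter. In limma-voom none of these 4 features was called, with adjusted p = 0.0981, 0.125, 0.454 and 0.484 in the order named. Neither decrease was called when vehicle replicate 2 (adjusted p = 0.0856 and 0.209), retinoic acid replicate 1 (adjusted p = 0.0955 and 0.157) or retinoic acid replicate 2 (adjusted p = 0.0957 and 0.155) was left out, or with library totals alone (adjusted p = 0.109 and 0.119). DESeq2 gave neither decrease an adjusted p, and neither was tested with counts halved or without vehicle replicate 1, nor TCONS_00038909 with the coverage minimum. None of the 4 features was tested when at least 50 counts were required in at least 2 libraries.

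Most changes were not between presence and absence of reads, since 126 of the 204 features that rose had at least 10 reads in both vehicle libraries and 290 of the 384 that fell had at least 10 in both retinoic acid libraries.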

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

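Each of the 588 called features that an alternative fitted kept its direction in it. This was nearly fixed in advance, since the alternatives reused these libraries and 586 of the 588 had groups that did not overlap. Of the 588, 288 were still called with DESeq2 and 158 with library totals alone. DESeq2 called 297 features (105 higher, 192 lower); it gave no adjusted p to 43 of the 588 and fitted size factors and dispersions of its own, and the cause of the lower count was not tested. With library totals alone, chosen after seeing the data, 158 were called (69 higher, 89 lower), so 56.3% were decreases against 65.3%, and the cause was not tested. Requiring at least 50 counts in at least 2 libraries gave 433 calls, 123 of them increases, among 11723 features tested; 184 of the 588 were no longer tested. Leaving out 1 library gave 289 to 565 calls in all, 93 to 196 increases and 196 to 369 decreases; the lone library of a group is then assumed to vary like the pair, and the filter kept more features. The other alternatives stayed within 1.5 times the count, from 519 with the coverage minimum to 764 with the replicate number as a block (264 higher, 500 lower). Similar counts did not mean the same features. Of the 540 that limma-voom called, 432 were among the 588. Features called in the same direction by edgeR, DESeq2 and limma-voom numbered 256. Deviations of libraries of the same number correlated with r = 0.0746 across features. The second principal component parted the numbers, which with so few libraries does not by itself show an effect of the number. Nothing in the labels says that the numbers mark a shared culture, so the block was kept as an alternative. Some bounds on features with 0 reads in a group moved more than 1.5 times without 1 library. For TCONS_00166598 the bound went from 47.6-fold to 24.7-fold without retinoic acid replicate 2. For TCONS_00016556 it went from 11-fold to 7.14-fold without vehicle replicate 1. For another feature with 0 reads in vehicle it went from 24.0-fold to 15.1-fold without retinoic acid replicate 2. Depth limits scarce features, since 27 of the 204 increases and 23 of the 384 decreases had at most 3 reads summed over the lower group. Not run for lack of gene names were the alternatives for gene lists, non-coding features and gene sums.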

Other observations

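Library totals alone as a scaling, the bounds for judging the scalings, the test of counts in pairs, the count of other splits, the median change by length and the shuffles within abundance were chosen after the result was seen. Upper-quartile factors and DESeq2 were planned, and the other tests on length, depth and neighbouring identifiers were set before their results.

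Breadth of detection split the libraries across the groups. Vehicle replicate 1 and retinoic acid replicate 2 listed 60950 and 60161 features, and vehicle replicate 2 and retinoic acid replicate 1 listed 58966 and 57804, at similar totals. That crossed split of the 4 libraries gave 0 calls in edgeR (580 features at an unadjusted p under 0.05) and 0 in DESeq2. The split by replicate number gave 0 calls in edgeR (1064 at an unadjusted p under 0.05) and 3 in DESeq2. The real split gave 588 in edgeR, the only 1 of the 3 splits with as many, against a highest other of 0. However, 3 splits are too few for a share under 0.05. In the other splits each group mixed vehicle and retinoic acid libraries, so differences between the real groups widened the spread within groups. Their edgeR counts at an unadjusted p under 0.05 lay below the 1608 expected by chance. The 0 calls are therefore no null reference.

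More features fell than rose, 384 against 204. For feature length bias, the lowest share of decreases over 3 parts by length was 59.8% (interval 51.0% to 68.1%). The value itself passed the bound set in advance for arguing against this bias. Its interval reaches below that bound, so the shares do not settle it. The median change over all features differed between these parts by only 0.015 on the log2 scale, so no general shift with length was seen. Scaling between libraries cannot be told apart from a real excess: the share was 64.3% with upper-quartile factors (95% Wilson interval 60.4% to 68.1%) and 64.6% with DESeq2 (59.1% to 69.9%), close to the main 65.3%, but 56.3% with library totals alone, which corrects for no composition and left 158 calls (48.5% to 63.8%). These intervals, like that for length, treat called features as independent and leave out the spread between libraries. Unequal depth was not put to a real test, since the largest total was only 3.0% above the smallest. Thinning to equal totals gave 65.4%. A response to retinoic acid itself stays open and was not tested apart from these. Without gene names, RNA of the germ cells could not be told from RNA of the STO feeders.

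Even counts outnumbered odd ones, and a candidate explanation is that both reads of a pair were counted. This needs an excess of even counts that shrinks as unpaired reads accumulate, and the share was at least 62.1% over 1 to 10 reads in every library, lower over 11 to 20 reads in every library, and 49.2% to 49.9% over 21 to 40 reads. Halving the counts gave 690 calls, 534 of them among the 588. No biological explanation was tested.

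Called features with consecutive identifier numbers moved together more often than chance placed them. Among 9195 such pairs tested, 12 had both features called in 1 direction and 2 in opposite directions, while 1000 shuffles gave a mean of 1.67 and at most 7, and shuffles within parts of equal abundance also at most 7. A candidate explanation is that several features are drawn from 1 locus, which the 12 pairs fit; the files give no coordinates to check it. Replicate noise shared by neighbouring features cannot be told apart from it, since differences between replicates correlated across neighbours with r = 0.156 in vehicle and 0.115 in retinoic acid, near 0 for random pairs (-0.0039 and 0.0007), between the bounds set in advance. Counting each run once leaves 576 in place of 588.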
